A study of Mus musculus with 63 samples.

How the data were processed

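Peritoneal macrophages of mice were profiled by RNA sequencing of polyadenylated RNA with a strand-directional library kit, per the labels' protocols. The animals were R1441C knock-in mice, in which the R1441C change was placed in their own Lrrk2 gene, or wild-type B6 mice, per the labels. Lrrk2 encodes leucine-rich repeat kinase 2, a large kinase with a GTPase domain that phosphorylates Rab proteins of the endolysosomal system, and R1441C is a change in that GTPase domain which is linked to inherited Parkinson's disease. Cells were drawn from the peritoneum 72 h after an injection of 3% thioglycollate, which recruits macrophages. They were left to adhere, and then received 100 U of interferon-gamma (IFN-γ) or vehicle for 18 h, per the labels' protocols. Per the study's design text, animals of both sexes were 2 to 3 months (young) or 18 to 21 months (old), and the labels form 16 groups of 63 libraries. Nothing in the counts shows the R1441C base change, so the genotype labels could not be checked.

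The authors deposited a table of whole-number read counts per gene and library, and a separate table of FPKM values for the same genes and libraries. Alignment with STAR 2.7.9a to GRCm39 and use of DESeq2 1.40.2 are named per the submitters' processing notes, and the read counter, the gene annotation and the strand setting are not given in the sources used here. The deposited FPKM values were checked against the deposited counts over 11796 genes. After 1 factor per gene and 1 factor per library were removed, the log ratio of both had a largest SD of 5.2e-10, so that FPKM added no measurement and only counts were tested. The count table lists 56748 genes, of which 17641 had no count in any library. Of the gene identifiers, 52073 were matched to a symbol in a GRCm38 annotation and 4675 were not. That annotation is of an earlier build than the authors' and was used only for symbols, gene kinds and for which genes lie near Lrrk2, so no coordinates are given. No part of the table named anything other than a gene.

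Total counts per library ran from 73.6 to 106.6 M with a median of 98.2 M, and 1 library lay below 85 M. Genes were kept by the filterByExpr function of edgeR with the 16 groups, which left 22147 genes with 99.992% of all counts, 21388 of them with a symbol. Counts were scaled with TMM factors, which lay between 0.886 and 1.233. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, in a single fit of all 63 libraries with 1 coefficient per group, so that every contrast shared the same estimate of the spread (median adjusted residual degrees of freedom 47). P-values were adjusted by Benjamini and Hochberg within each contrast and called at 0.05. All p-values of single genes printed here are adjusted values from this edgeR fit unless another test is named. Levels are counts scaled to library size with TMM factors (CPM), given as mean ± SD with n libraries, and changes are log2 fold changes with their standard errors. Where all libraries of a group had a count of 0, the change was given as a lower bound against a floor of 3 counts over the group.

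The contrasts were the genotype effect (knock-in against wild-type) in each of 8 strata of sex, labelled age and labelled treatment, the effect of the IFN-γ label averaged over the strata within each genotype, the effect of the age label in untreated libraries of each genotype and sex, and the interactions of genotype with treatment, age and sex. Interactions are given as the knock-in effect minus the wild-type effect, and those with sex as the female effect minus the male effect. Gene lists of at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with its preset correlation, by camera with the correlation estimated from the data, and by the fry rotation test, with adjustment over the lists within each contrast. Beside each count of list members over all genes tested, the count adjusted over the list alone is given. Genes near Lrrk2 were compared with other tested genes by Fisher's exact test (two-sided) within 10 Mb, with 5 and 20 Mb as alternatives. The contrasts, lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

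Genes were named by a fixed rule. Lrrk2 and lists of sex-linked genes and of genes that differ between C57BL/6 substrains were always examined, and of these Lrrk2, Xist, Ddx3y and Nnt are printed. In each genotype stratum, up to 5 genes higher and 5 lower with the largest change were named among those called with a mean of at least 1 CPM in the higher group, for the IFN-γ label up to 12 each way in wild-type with the values of both genotypes, for each age contrast up to 5 each way and for each interaction up to 3 each way. Up to 4 members of each list that passed the list test were named, by smallest p, and genes called in the same direction in at least 6 of the 8 strata, up to 12. Predicted genes without a proper name, pseudogenes and segments of immunoglobulin or T cell receptor genes were counted and not named. Reads of near-identical genes (haemoglobin, immunoglobulin, Serpina3, guanylate-binding protein and MHC genes) may have been split in counting, and with the strand setting unknown a gene and its antisense partner cannot be told apart. A few genes outside the rule are named with a statement that they were chosen after their values were seen.

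Alternatives were scaling by RLE size factors, no expression filter, a fit of only the groups of each contrast, the Wald test of DESeq2 1.42.0, the replicate number as a block, and leaving out each library of a contrast in turn. Joining near-identical libraries of a group, leaving out 4 doubted libraries and leaving Irak4 out of the genes near Lrrk2 were added after the data were seen. The computations were tested on simulated counts for the 22147 tested genes, with 50 genes changed at each fold. Counts were drawn from each gene's mean over all libraries, its spread and the real library sizes. Libraries were drawn independently, so near-identical libraries were not imitated. For the genotype contrast in young untreated females, 62% of genes changed 1.5-fold and 90% of those changed 2-fold were recovered, and 8.5% of the calls were false. For male old untreated libraries the values were 60%, 90% and 3.3%, and for the interaction of genotype and age in untreated males 26%, 52% and 10.6%.

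To compare the immunoglobulin repertoire between libraries, 148 variable (V) gene segments with at least 200 counts in total were taken. The logarithm of each segment's share of a library's V counts, with 100 ppm added, was centred per segment over libraries, and Pearson's r over segments was computed for each pair of libraries, with r above 0.4 as threshold. In simulated repertoires, 20 of 20 pairs of libraries drawn from the same repertoire and 0 of 760 unrelated pairs passed it. Their V counts lay in the range of libraries labelled untreated. The pairs of the same simulated repertoire had an r of 0.82 or more, so they do not imitate real pairs of lower r. This measure was chosen after the data were seen. Nothing in the labels states which libraries came from which animal, and libraries are counted as separate replicates, so p-values measure only the spread between these libraries, which may be technical in part. Groups were taken from the sample description throughout. For 3 knock-in male old untreated libraries (replicates 2, 4 and 5) another field of the labels names IFN-γ, and they were kept as untreated.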

Results

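RNA of thioglycollate-elicited peritoneal macrophages was sequenced in 63 libraries that the labels divide by Lrrk2 genotype (wild-type or R1441C knock-in), sex, age and treatment with IFN-γ into 16 groups. The study asked, per its design text, how the R1441C change alters macrophage functions such as antigen presentation, cytokine production, phagocytosis and lysosomal function, and whether this depends on sex and age. Wild-type females were represented by 5 old IFN-γ, 5 old untreated, 3 young IFN-γ and 3 young untreated libraries, and wild-type males by 5, 3, 5 and 3. Knock-in females were represented by 5 old IFN-γ, 5 old untreated, 2 young IFN-γ and 5 young untreated libraries, and knock-in males by 5, 3, 3 and 3. Group means of total counts lay between 89.4 ± 13.7 M (wild-type young IFN-γ females, n = 3) and 101.3 ± 1.35 M (knock-in old untreated males, n = 3).

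Lrrk2, the targeted gene, was measured in every library. Its group means were 25.3 to 62.3 CPM in libraries labelled young, apart from 105 ± 68.4 CPM in wild-type young IFN-γ females (n = 3), and 109 to 169 CPM in libraries labelled old. Lrrk2 was not called between the genotypes in any of the 8 strata, with log2 changes from -0.75 ± 0.34 (adjusted p = 0.174, young IFN-γ females) to 0.41 ± 0.23 (adjusted p = 0.32, old untreated females). It was higher in libraries labelled old than in those labelled young among untreated cells, by a log2 change of 1.96 ± 0.29 in wild-type females (adjusted p = 1.79e-07) and 2.52 ± 0.32 in knock-in males (adjusted p = 5.46e-09). With the IFN-γ label it rose by 0.69 ± 0.14 in wild-type (adjusted p = 1.07e-04) and was not called in knock-in (0.13 ± 0.14, adjusted p = 0.673). The female transcript Xist and the Y-linked Ddx3y matched the sex label in all but 2 libraries. Knock-in old IFN-γ females 4 and 5 had 1.69 and 1.55 CPM of Xist, against 120.1 CPM or more in the other females and 14.7 CPM or less in males, and 0.624 and 0.601 CPM of Ddx3y, against 33.9 CPM or more in males. Ddx3y reached 8.93 CPM in wild-type young IFN-γ females (4.98 ± 4.47, n = 3) and was at 4.13 and 4.37 CPM in knock-in young untreated females 2 and 5. Among males, Xist was at 13.8 CPM in knock-in young untreated 3 and at 13.4 and 14.7 CPM in wild-type young IFN-γ 4 and 5. Nnt, which carries a deletion in the C57BL/6J substrain, had group means of 0.122 to 0.22 CPM.

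Genes that respond to IFN-γ separated the libraries by the age label and not by the treatment label. Gbp2, an IFN-γ-induced guanylate-binding protein, was at 4372 to 7510 CPM in the 36 libraries labelled old and at 13.5 to 883 CPM in the 27 labelled young. In wild-type females, Gbp2 was at 85.2 ± 96.8 CPM in young untreated (n = 3), 744 ± 122 CPM in young IFN-γ (n = 3), 6835 ± 762 CPM in old untreated (n = 5) and 4989 ± 526 CPM in old IFN-γ libraries (n = 5). The chemokine Cxcl9, the MHC class II transactivator Ciita and the nitric oxide synthase Nos2 likewise showed 0 libraries out of place by the age label. By the treatment label, 47.1% of the pairs of treated and untreated libraries had the higher Gbp2 in the treated library. Transcripts of B cells followed the treatment label. Cd79a, a part of the B cell receptor, was at 4.92 to 311 CPM with the IFN-γ label and at 1.42 to 12.3 CPM without it, and 95.9% of the pairs had the higher value in the library labelled IFN-γ, against 55.3% by the age label. These levels stand against both labels as given, and every age or treatment comparison below is between the labels, with its direction open to that doubt.

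**Figure D1:**
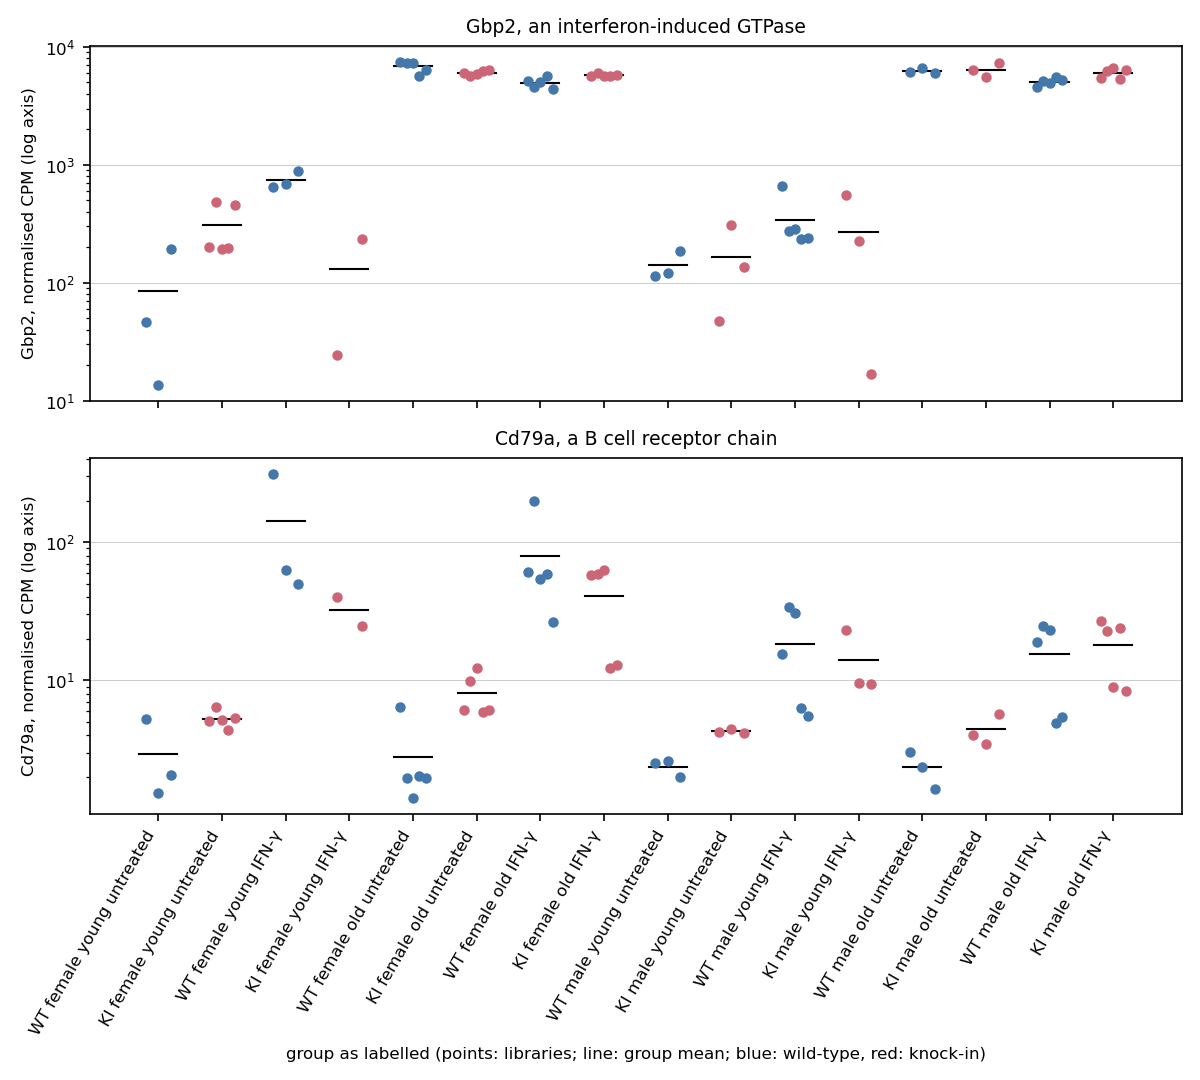
Gbp2 (top) and Cd79a (bottom) in CPM on log axes by labelled group, with points for libraries (blue wild-type, red knock-in) and a line at each group mean. Gbp2 is at 4372 CPM or more in each library labelled old and at 883 CPM or less in each labelled young, and Cd79a is above 12.3 CPM only in libraries labelled IFN-γ.

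Use of immunoglobulin V segments, which differs between the B cell repertoires of individual animals, was compared between libraries. V-segment counts were 1917 to 57242 in libraries labelled IFN-γ and 701 to 2530 in those labelled untreated. Among pairs alike in genotype, sex and labelled treatment but differing in labelled age, 18 of 123 exceeded an r of 0.4 across segments, and the highest r was 0.94. All of these were among the 65 such pairs labelled IFN-γ, while 0 of the 58 labelled untreated passed (highest r 0.23). Within groups, 13 of 102 pairs passed (highest r 0.91). None passed among 123 pairs that differed only in labelled treatment (highest r 0.26), among 119 that differed in both labels (0.27), or among 1486 that differed in genotype or sex (0.38). Each of the 123 and 119 pairs held an untreated library with 2530 V counts or fewer. Their lack of passing pairs thus cannot tell whether treated and untreated libraries share animals. Segments within a library are not independent of each other, and the threshold was chosen after the data were seen.

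**Figure D2:**
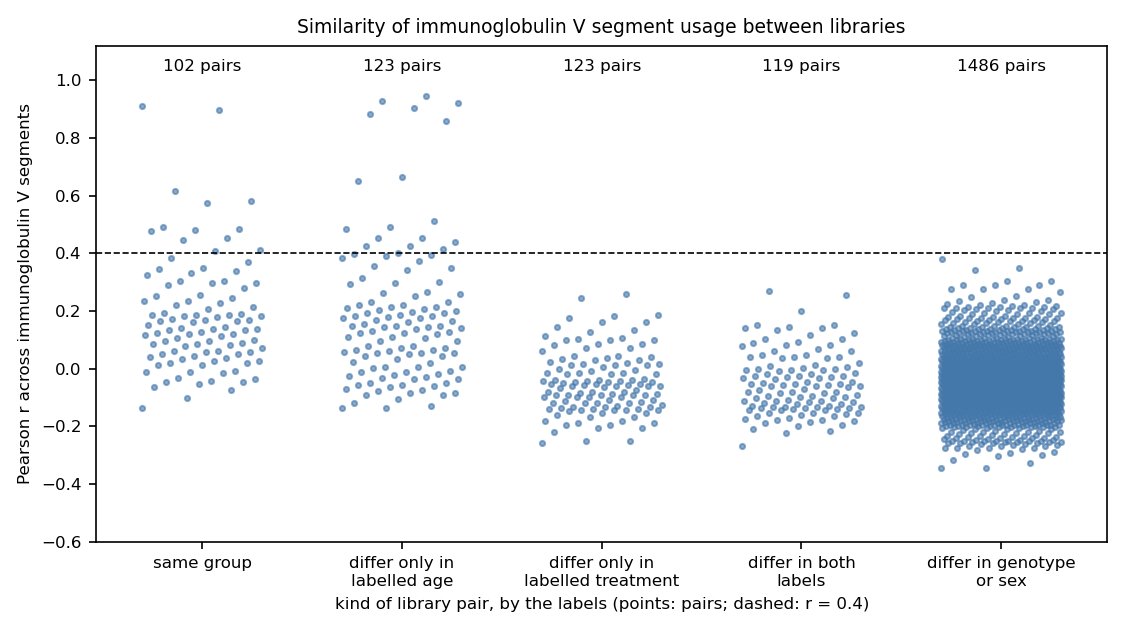
Pearson's r over immunoglobulin V segments for each pair of libraries (points), grouped by the labels in which the libraries differ. Values above the line at 0.4 occur within groups and between libraries that differ in labelled age only, up to 0.94.

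Among untreated libraries, those labelled old were compared with those labelled young to describe the effect of age in each genotype and sex. In wild-type females, the connexin gene Gja4 had no count in the young group and was at least 240-fold higher. Cxcl9, a chemokine that draws T cells and is induced by IFN-γ, went from 16.5 ± 15.6 (n = 3) to 1817 ± 1272 CPM (n = 5; log2 change 6.78 ± 1.07, adjusted p = 6.21e-07), and Nos2 rose by 6.73, the ubiquitin-like gene Ubd by 6.82 and the serine protease inhibitor Serpina3g by 6.93. Old library 1 held 4070 CPM of Cxcl9 and 907 CPM of Nos2, against 1090 to 1550 and 121 to 147 CPM in the others of that group. Mamdc2, a secreted protein with MAM domains, fell from 336 ± 41.0 to 14.0 ± 1.61 CPM (-4.59 ± 0.38, adjusted p = 1.3e-14), and the guidance receptor Robo2 (-4.70), the organic anion transporter Slco2b1 (-4.63), Shisa9 (-4.60) and Tceal7 (-4.57) fell as well. In wild-type males, Gja4 (7.85), the cystatin Cst7 (6.47), the apolipoprotein L gene Apol6 (6.34), Nos2 (6.33) and Ubd (6.27) rose most, and Slco2b1 (-4.75), Mamdc2 (-4.65), the Wnt antagonist Dkk2 (-4.56), the costimulatory receptor Cd28 (-4.55) and Tceal7 (-4.51) fell most.

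Knock-in libraries showed like changes between the age labels. In knock-in females, Nos2 (6.23), Cst7 (5.33), Cxcl9 (4.96) and the Fc receptor-like gene Fcrl6 (4.94) were among the genes that rose most, and Dkk2 (-4.95), Cd28 (-4.53), Mamdc2 (-4.42), Tceal7 (-4.34) and the transporter Abca6 (-4.21) fell most. In knock-in males, Nos2 (6.58), Gja4 (6.38), Cxcl9 (6.22), Cst7 (6.17) and Hcar2 (5.71), a receptor for hydroxycarboxylic acids, rose most, and Bex1 (-4.64), Cd28 (-4.49), Mamdc2 (-4.28), Slco2b1 (-4.25) and Tceal7 (-4.06) fell most. Cxcl9 went from 61.0 ± 33.2 to 1896 ± 732 CPM in knock-in females (n = 5 each) and from 35.2 ± 26.1 to 2628 ± 1392 CPM in knock-in males (n = 3 each). The number of genes called was 9861 in wild-type females (4870 higher and 4991 lower), 8163 in wild-type males (4147 and 4016), 9917 in knock-in females (4869 and 5048) and 7110 in knock-in males (3640 and 3470).

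Gene lists showed the breadth of this difference. Of 37 genes of the IFN-γ response, 35 rose in wild-type females, 36 in wild-type males and 37 in both knock-in sexes (36, 37, 37 and 37 adjusted over the list alone), with median log2 changes of 4.93, 4.67, 3.81 and 4.60. Of 33 genes stimulated by type I interferon, such as Bst2 (2.22) and Rtp4 (3.07) in wild-type females, 32 rose in each contrast, and the same number adjusted over the list alone. Of 14 genes of MHC class II presentation, 10 rose in each and 1 fell in each but wild-type females, where 0 fell (the same counts adjusted over the list alone), and the invariant chain Cd74 went from 225 ± 109 (n = 3) to 4871 ± 697 CPM (n = 5) in wild-type females. Of 23 genes of MHC class I presentation, which include the proteasome activator Psme1 (2.40) and the peptide transporter Tap2 (2.24), 23 rose in each contrast (23 adjusted over the list alone). These 4 lists kept their call with an estimated correlation, with adjusted p = 0.00029 for MHC class I in wild-type males and 0.0478 for type I interferon in wild-type females.

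Costimulatory genes such as Icam1, Cd40 and Cd86 rose in 9 (wild-type females and males), 10 (knock-in females) and 9 (knock-in males) of 14, and 1 fell in each (9, 10, 10 and 10 higher and 1 lower adjusted over the list alone). The adjusted p with an estimated correlation was 0.0532 and 0.0631 in wild-type females and males, and 0.0381 and 0.0153 in knock-in females and males. Of 22 genes of the unfolded protein and integrated stress response, among them the chaperone Hspa5 (1.16 in wild-type females) and Creld2 (1.79), 16, 17, 16 and 16 rose and 2, 1, 3 and 1 fell (16, 18, 16 and 16 higher and 2, 3, 3 and 1 lower adjusted over the list alone). That list kept its call with an estimated correlation except in knock-in females (adjusted p = 0.0734). Of 75 nuclear genes of oxidative phosphorylation, 72, 64, 61 and 50 rose (74, 67, 61 and 55 adjusted over the list alone), with Cycs, cytochrome c, at 1.81 ± 0.09 in wild-type females. This call was lost with an estimated correlation, at adjusted p = 0.152, 0.212, 0.41 and 0.36. B cell markers did not move with the age label in untreated libraries, with 0 of 22 higher and 1 lower in each contrast and an adjusted p of 0.771 or more.

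The effect of the IFN-γ label was estimated within each genotype as the mean over sexes and labelled ages. In wild-type, Prss35 rose most (5.38), and lymphocyte genes were among those that followed. Cd79a rose by 4.02 ± 0.36 (adjusted p = 5.63e-12), the B cell transcription factors Ebf1 and Pou2af1 by 4.24 and 4.14, the B cell kinase Blk by 4.12, the IgE receptor Fcer2a by 4.2, Dtx1 by 4.17, the T cell genes Cd8b1 and Ctla4 by 4.19 and 4.02, and Fam169b, Scn4a and Ppp1r16b by 4.21, 4.04 and 4.02. In knock-in, Cd79a rose by 2.18 ± 0.33 (adjusted p = 8.37e-06), Ebf1 by 1.98, Pou2af1 by 2.31, Blk by 2.57, Fcer2a by 2.40, Dtx1 by 2.34, Cd8b1 by 1.69, Ctla4 by 4.59, Fam169b by 2.55, Scn4a by 3.28 and Ppp1r16b by 2.29, and Prss35 was not called (0.84 ± 1.47). Eef1a2, a translation factor, fell by 2.00 in wild-type and by 1.38 in knock-in, and Mfge8, which binds apoptotic cells, fell by 1.77 and by 0.63 (adjusted p = 0.0391). Map6, Trim29 and Npas2 fell by 1.32, 1.29 and 1.27 in wild-type and by 0.61, 0.52 and 0.55 in knock-in. Ctsk, the lysosomal protease cathepsin K, fell by 1.36 ± 0.18 in wild-type and was at -0.04 ± 0.19 in knock-in (adjusted p = 0.948). Mylk2, Klhl38, Sdk2, Bex1, Htr2b and Pla2g2e fell by 1.74, 1.55, 1.4, 1.39, 1.37 and 1.31 in wild-type and were not called in knock-in, where the lowest adjusted p was 0.0617 for Mylk2. The difference between the genotypes was tested only within each sex and age.

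Of 22 B cell markers, 21 rose and 1 fell in wild-type (21 and 1 adjusted over the list alone; median 3.87), and 20 rose in knock-in (21 adjusted over the list alone; median 2.17), among them Ighm (2.51) and Igkc (2.90). The adjusted p was 0.0926 and 0.168 with an estimated correlation. Of 26 T and NK cell markers, such as Cd3d (3.58) and Eomes (3.62) in wild-type, 21 rose and 1 fell in wild-type and 13 rose in knock-in (21 and 1, and 17 with 2 lower, adjusted over the list alone), at adjusted p = 0.0926 and 0.49 with an estimated correlation. Markers of mast cells and basophils such as Mcpt4 (3.80) and Kit (2.02) rose in 10 of 12 in wild-type (10 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). Beside these cell markers, IFN-γ response genes had a smaller median: 29 of 37 rose and 1 fell in wild-type (30 and 1 adjusted over the list alone), with a median of 0.79 and Gbp9 at 0.86 ± 0.13, and adjusted p = 0.206 with an estimated correlation. This is a mean over strata. In wild-type young females the mean log2 CPM over the list was 2.51 to 4.18 untreated and 5.34 to 5.72 with IFN-γ, and in wild-type old females 7.76 to 8.05 and 7.84 to 8.30. MHC class II genes rose in 11 of 14 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation), led by H2-Ob (3.39) and H2-Eb2 (3.84), which B cells express.

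Lysosomal genes, part of the study's question, fell with the IFN-γ label in wild-type. Of 63 lysosomal hydrolases and membrane proteins, 41 fell and 1 rose (43 and 3 adjusted over the list alone), including the phosphatase Acp5 (-0.64) and the lipid transfer protein Gm2a (-0.40), at adjusted p = 0.28 with an estimated correlation. Of 19 subunits of the V-ATPase, the lysosomal proton pump, 16 fell (18 adjusted over the list alone), with Atp6v1e1 at -0.36 ± 0.05 and Tcirg1 at -0.46 ± 0.08, and adjusted p = 0.206 with an estimated correlation. Libraries old 2 and young 1 of the wild-type IFN-γ females stood apart, at a mean log2 CPM of 7.53 and 7.76 over the lysosomal list (8.22 to 8.47 in the other wild-type IFN-γ libraries) and 6.89 and 6.87 over the V-ATPase list (7.59 to 7.90). In knock-in, 30 of 33 proliferation genes fell (33 adjusted over the list alone; median -0.70), such as Tpx2 (-0.70) and the cyclin Ccnb1 (-1.08), and the adjusted p was 0.168 with an estimated correlation. In the same contrast, 9 of 20 mesothelial and fibroblast markers fell and 1 rose (13 and 1 adjusted over the list alone), with Krt19 at -1.49 and mesothelin (Msln) at -1.06, and 5 of 5 red cell markers rose (5 adjusted over the list alone), with Hbb-bs at 3.63 ± 0.72. Both had adjusted p = 0.672 with an estimated correlation. In all, 6939 genes were called in wild-type (3418 higher, 3521 lower) and 1721 in knock-in (742 higher, 979 lower). The knock-in count fell to 1052 without young IFN-γ female 1 and rose to 3008 without 4 doubted libraries. With near-identical libraries joined the counts were 3421 in wild-type and 1108 in knock-in.

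The genotype effect was tested in each stratum, that is, within sex, labelled age and labelled treatment. In untreated females labelled young, knock-in libraries (n = 5) had more of several immune genes than wild-type (n = 3). Gbp7, a guanylate-binding protein, was at 36.4 ± 17.8 against 12.5 ± 3.73 CPM (log2 change 1.54 ± 0.36, adjusted p = 0.0298), the NK receptor Klrk1 at 2.17 ± 0.70 against 0.613 ± 0.521 CPM (1.82 ± 0.42, adjusted p = 0.0272), and the checkpoint ligand Pdcd1lg2, the actin-binding calponin Cnn3 and the metalloprotease Mmp25 rose by 1.57, 1.46 and 1.45. Robo2 (-1.26), Catsperg1 (-1.14), the chromatin reader Ing4 (-1.13), the kinesin Kifc2 (-0.95) and Acrbp (-0.92) were lower. Of the 37 IFN-γ response genes 3 were called higher (28 adjusted over the list alone; median 1.05), namely Gbp7, Ifi205 (0.78) and Ifi47 (1.32), and of 14 MHC class II genes 1, H2-DMb1 (0.68, adjusted p = 0.028; 7 adjusted over the list alone). Both had adjusted p = 0.146 with an estimated correlation. Some libraries stood apart in Gbp2. Knock-in libraries 2 and 5 held 485 and 459 CPM, and also Ddx3y at 4.13 and 4.37 CPM. Knock-in libraries 1, 3 and 4 held 192 to 201 CPM of Gbp2, near wild-type library 5 (195), while wild-type libraries 1 and 4 held 46.8 and 13.5 CPM. Of 33 proliferation genes 0 were called (12 adjusted over the list alone; adjusted p = 0.256 with an estimated correlation). Lists of other cell types moved too. Mean log2 CPM was 3.03 to 3.26 in knock-in against 1.56 to 2.73 in wild-type libraries over mesothelial and fibroblast markers, 4.56 to 4.63 against 3.83 to 4.49 over monocyte markers and 1.15 to 1.22 against 0.81 to 0.97 over eosinophil markers. By edgeR 0 members of these 3 lists were called (0 adjusted over the list alone), and the adjusted p with an estimated correlation was 0.363, 0.44 and 0.152. In all, 100 genes were called, 52 higher and 48 lower, of 3250 with an unadjusted p under 0.05. RLE scaling gave 77 higher and 38 lower, and DESeq2 gave 253 and 99. With near-identical libraries joined 6 were left. The count was 3 without wild-type library 1 and 411 without wild-type library 5, and 6 of the 8 refits without 1 library moved it by over 1.5 times.

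In females labelled young and IFN-γ, 2 knock-in libraries were compared with 3 wild-type libraries. IFN-γ response and antigen presentation genes were lower in knock-in. Cd74 was at 386 ± 132 against 1234 ± 447 CPM (-1.68 ± 0.32, adjusted p = 0.00101), the peptide loader H2-DMa at 44.2 ± 15.6 against 124 ± 16.2 CPM, and the cytokine signalling inhibitor Socs3 at 22.6 ± 4.84 against 62.1 ± 14.1 CPM. The taste-pathway channel Trpm5 (3.84 ± 0.59, adjusted p = 2.78e-05), the transcription factor Pou2f3 (6.32), Avil (4.06) and Sh2d7 (7.62) were higher, and Rgs21 was at least 234-fold higher, while the leptin receptor Lepr (-5.97), Serpinb2 (-4.87), Ofcc1 (-4.80), Prss35 (-4.73) and the calcium channel Cacna1h (-4.57) were lower. In wild-type, Lepr was at 10.6 ± 17.7, Serpinb2 at 120 ± 194, Ofcc1 at 1.63 ± 2.52, Prss35 at 2.81 ± 3.96 and Cacna1h at 1.23 ± 1.38 CPM, each with an SD above its mean. Lepr was at 31.1 CPM in wild-type library 1. Knock-in library 1 was low in IFN-γ response genes. Its mean log2 CPM over that list was 2.98, against 4.65 in knock-in library 2 and 5.34 to 5.72 in wild-type, and it had 24.3 CPM of Gbp2 against 235 CPM in library 2. Of 37 IFN-γ response genes 23 fell (29 lower and 1 higher adjusted over the list alone; median -1.54), of 14 MHC class II genes 8 (11 adjusted over the list alone) and of 23 MHC class I genes 10 (12 adjusted over the list alone), such as Psmb10 (-0.73) and Tap1 (-0.90). All 3 lists had adjusted p = 0.08 with an estimated correlation. Markers of other cells fell with them: 4 of 15 monocyte markers (9 adjusted over the list alone; adjusted p = 0.08 with an estimated correlation), with Ly6c2 at -3.70, 11 of 26 T and NK cell markers (15 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation), with Klrk1 at -3.18, and 5 of 22 B cell markers (16 adjusted over the list alone; adjusted p = 0.307 with an estimated correlation), with Vpreb3 at -3.17. Wild-type library 1 stood apart in some of these lists. Its mean log2 CPM was 6.17 over the B cell list (3.66 and 3.76 in the other wild-type libraries, 3.62 and 2.91 in knock-in). It was 5.97 over the monocyte list (4.70 and 4.94; 3.86 and 4.22) and 8.13 over the MHC class II list (6.87 and 7.52; 6.33 and 6.56). Of 36 inflammatory cytokines and chemokines 10 fell (16 lower and 1 higher adjusted over the list alone; adjusted p = 0.08 with an estimated correlation). In all, 1493 genes were called, 653 higher and 840 lower, and DESeq2 gave 439 higher and 1115 lower. The count was 916 without 4 doubted libraries, among them wild-type library 1 with the lowest total counts. These groups had no near-identical libraries to join, and with those of other groups joined it was 692. It was 105 without knock-in library 1, 539 without wild-type library 1, 2220 without wild-type library 2, and 0 in an edgeR fit of only these 5 libraries (2310 at an unadjusted p under 0.05).

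**Figure D3:**
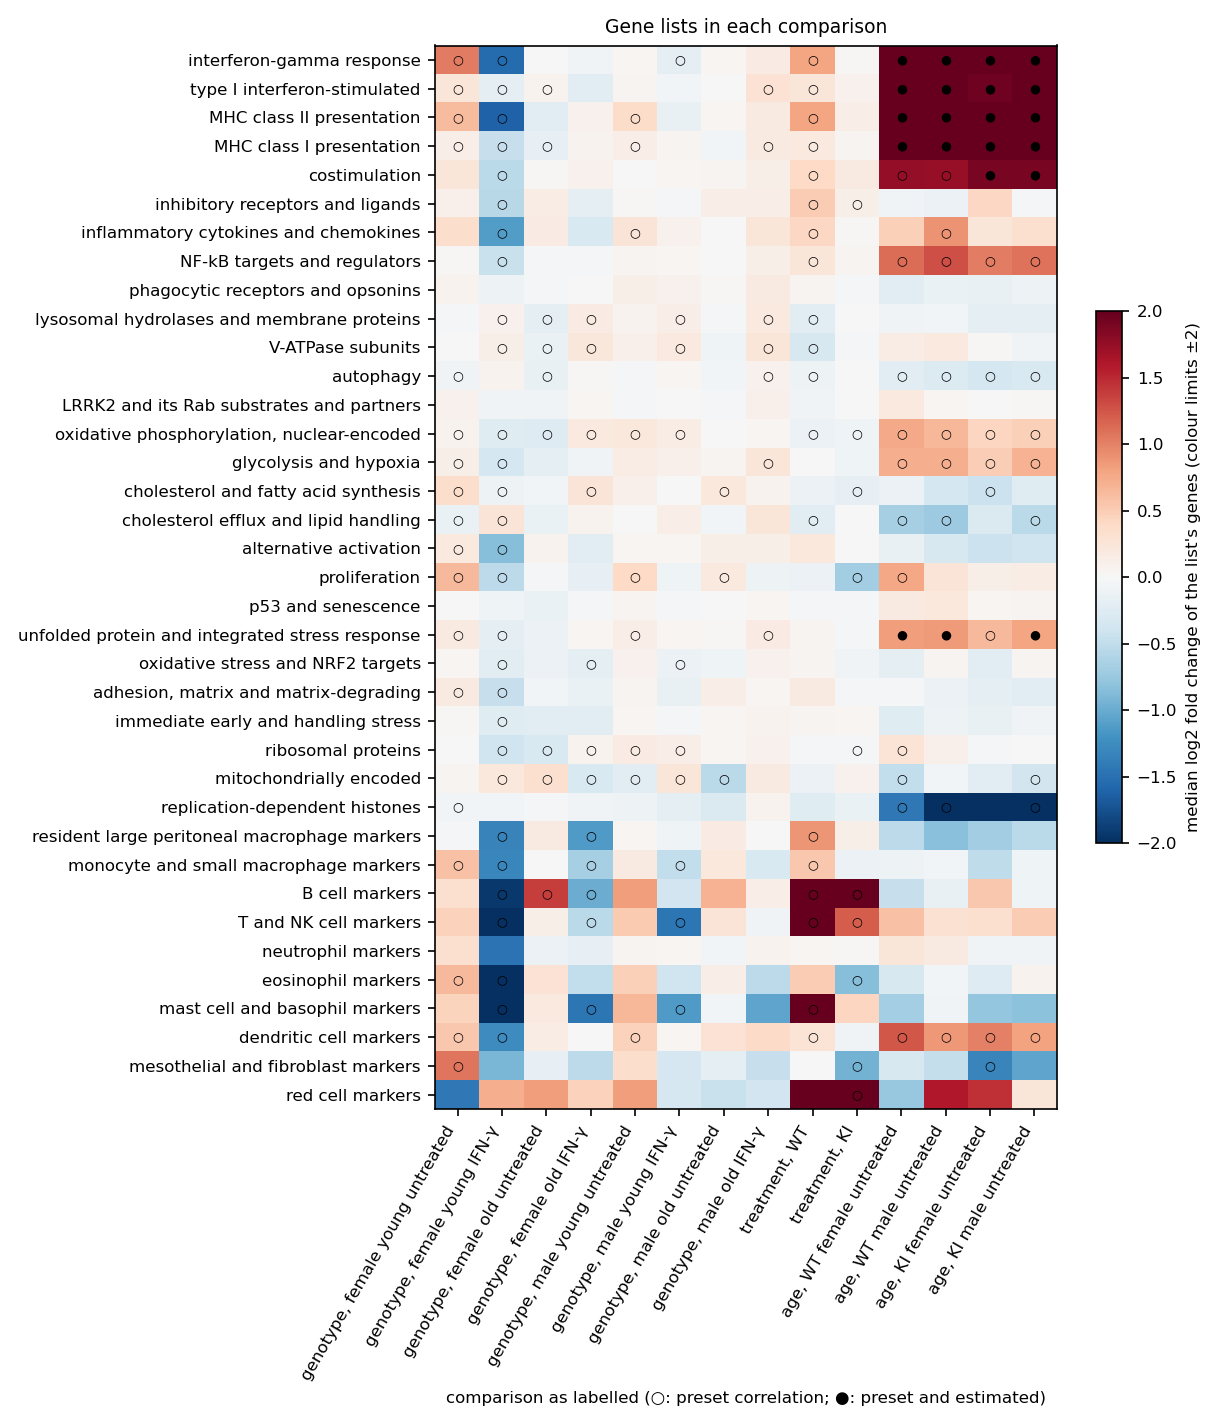
Heatmap of the median log2 fold change of each gene list (vertical axis) in the genotype, treatment and age comparisons as labelled (horizontal axis), with colours limited to ±2. Open circles mark lists called with the preset correlation and filled circles those called with the estimated correlation too, and the filled ones lie in the age comparisons, as for the IFN-γ response list with a median of 4.93 in wild-type females.

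In untreated females labelled old (n = 5 each), Irak4, a kinase of Toll-like receptor signalling, was lower in knock-in at 34.8 ± 2.21 against 54.8 ± 3.89 CPM (-0.66 ± 0.06, adjusted p = 3.45e-10). The other 3 of 4 called genes were of kinds not named here. Of 75 oxidative phosphorylation genes 0 were called (66 lower adjusted over the list alone; adjusted p = 0.52 with an estimated correlation), and of 75 ribosomal protein genes 0 (68 lower and 1 higher adjusted over the list alone; adjusted p = 0.52 with an estimated correlation). Knock-in libraries 1, 2 and 3 were low in both lists while 4 and 5 lay in the wild-type range, as given below for the interaction with treatment. The edgeR call of 2 higher and 2 lower stood against 4427 genes with an unadjusted p under 0.05, and RLE scaling gave 38 higher and 3 lower and DESeq2 314 and 82. Without knock-in library 4 the count was 2788 and without knock-in library 1 it was 1, and each of the 10 refits without 1 library moved it by over 1.5 times.

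In females labelled old and IFN-γ (n = 5 each), Trpm5 was higher in knock-in, at 1.97 ± 2.59 against 0.196 ± 0.175 CPM (3.34 ± 0.54, adjusted p = 4.58e-05). In knock-in, 3 of 5 libraries were at 1.68 to 6.36 CPM and 2 did not exceed the wild-type range. There, Avil (2.60), the kinase Camk2b (2.38), the keratin Krt18 (1.77) and Rgs13 (1.75) were higher. The protease inhibitor Slpi was at 55.3 ± 22.5 against 542 ± 924 CPM (-3.29 ± 0.57, adjusted p = 3.21e-04), and the platelet receptor Gp6 (-4.50), the serotonin-synthesis enzyme Tph1 (-4.29), Cacna1h (-4.23) and Serpinb2 (-3.84) were lower. In wild-type, Gp6 was at 1.78 ± 3.64, Tph1 at 1.74 ± 2.33, Cacna1h at 1.42 ± 1.76 and Serpinb2 at 18.5 ± 36.1 CPM, each with an SD above its mean, and the last 2 overlapped between the genotypes. Of 21 markers of resident large peritoneal macrophages 9 fell (12 lower and 1 higher adjusted over the list alone), with Gata6, the transcription factor of these cells, at 1.95 ± 0.69 against 4.60 ± 2.22 CPM, and of 12 mast cell and basophil markers 4 fell (8 adjusted over the list alone), with Mcpt4 at -3.11 and Cpa3 at -2.31. Of 63 lysosomal genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with Gm2a at 1159 ± 66.2 against 772 ± 218 CPM, and of 20 oxidative stress and NRF2 target genes 5 fell (7 lower and 2 higher adjusted over the list alone), with the cystine transporter Slc7a11 at -2.22. Each of these 4 lists had adjusted p = 0.702 with an estimated correlation. Wild-type library 2 stood apart in them. Its mean log2 CPM was 7.53 over the lysosomal list (8.22 to 8.40 in the other wild-type libraries, 8.31 to 8.42 in knock-in). It was 7.51 over the NRF2 list (6.42 to 6.58; 6.31 to 6.70), 6.45 over the resident macrophage list (4.60 to 4.84; 3.26 to 4.80) and 2.25 over the mast cell list (0.90 to 1.76; 0.12 to 1.05). In all, 1286 genes were called, 467 higher and 819 lower. The count was 140 without wild-type library 2, which held 2200 CPM of Slpi, and 2587 without wild-type library 4. It was 380 without the doubted libraries (among them wild-type 2, and knock-in 4 and 5 with little Xist), 55 with near-identical libraries joined, and 3 in a fit of only these groups.

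Between the genotypes in males, few genes were called outside the stratum labelled old and IFN-γ. In untreated males labelled young (n = 3 each) 3 genes were called, 1 higher and 2 lower, of which Exosc1, a subunit of the RNA exosome, was named by the rule (14.1 ± 1.17 against 11.1 ± 0.30 CPM, 0.34 ± 0.07, adjusted p = 0.0454). RLE scaling gave 0 higher and 2 lower and DESeq2 6 and 7, and the count was 0 without knock-in library 2 and 31 without knock-in library 3. In males labelled young and IFN-γ (3 knock-in, 5 wild-type), the inhibitory receptor Pirb was at 863 ± 53.9 against 680 ± 22.9 CPM (0.34 ± 0.08, adjusted p = 0.0311) and the transglutaminase Tgm1 rose by 0.91, while the clock repressor Nr1d1 (-0.89, adjusted p = 0.0289), Acsbg1 (-3.46), the prostaglandin D synthase Ptgds (-7.65) and Irak4 (-0.40) were lower and the sperm protamine Prm2 was at least 174-fold lower. Ptgds was at 10.7 CPM in wild-type libraries 4 and 5 and at 0.0191 to 0.0386 CPM in the other 3, and Prm2 at 4.52 and 3.99 CPM in the same 2 libraries (1.77 ± 2.27 over the group), so both rest on 2 libraries. These 2 were near-identical (root mean square log2 difference 0.149) and are not shown to be separate animals. Here 33 genes were called, 10 higher and 23 lower, with 11 without knock-in library 3 and 58 without wild-type library 1. In untreated males labelled old (n = 3 each) the only call was Irak4 (37.2 ± 3.41 against 51.6 ± 6.96 CPM, -0.47 ± 0.08, adjusted p = 0.0056), with 767 genes at an unadjusted p under 0.05 and 2 higher and 1 lower by DESeq2. It was lost in 3 of 6 refits without 1 library, such as that without knock-in library 2. Of 13 mitochondrially encoded genes there, 0 were called (10 lower adjusted over the list alone; median -0.53; adjusted p = 0.069 with an estimated correlation).

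In males labelled old and IFN-γ (n = 5 libraries each), lysosomal and autophagy genes were among those higher in knock-in. Joining near-identical libraries left 2 units in wild-type and 4 in knock-in, with 12 genes called. The SD and p-values below, which count 5 libraries each, may thus understate the spread between animals. Progranulin (Grn), a lysosomal growth factor, was at 2726 ± 197 against 2212 ± 99.5 CPM (0.30 ± 0.08, adjusted p = 0.0288), the acid glucosidase Gaa rose by 0.25, Plbd2 by 0.28 and the lysosomal membrane protein Laptm5 by 0.36. Of 63 lysosomal genes 7 rose (20 higher and 1 lower adjusted over the list alone), of 19 V-ATPase subunits 3 (7 adjusted over the list alone), with Atp6v1d at 0.34, and of 30 autophagy genes 4 (6 higher and 1 lower adjusted over the list alone), with Atg3 at 0.26, Gabarapl1 at 0.45 and the cargo receptor Sqstm1 at 0.38. All 3 lists had adjusted p = 0.71 with an estimated correlation. Zfp972 (1.44), Prss46 (1.39), the interferon-induced membrane protein Ifitm1 (1.13), Sez6l2 (1.01) and the hyaluronidase Hyal1 (0.97) rose most. Angiotensinogen (Agt) was at least 667-fold lower and Akr1cl at least 360-fold lower, and Ptgds (-10.41), Ccn5 (-6.80) and Mgarp (-4.11) were lower. In knock-in, Ptgds was at 0.0106 CPM in library 2, near the limit of counting, and at 0 in the others, so the size of its change is uncertain. In wild-type, Ptgds was at 4.63 ± 6.31, Agt at 3.98 ± 5.43, Akr1cl at 2.15 ± 2.87 and Ccn5 at 1.33 ± 1.76 CPM, each with an SD above its mean, as it was for Mgarp. Ptgds, Agt, Akr1cl and Ccn5 were highest in wild-type libraries 4 and 5 (Agt 10.2 and 9.61 CPM, Akr1cl 5.5 and 5.07 CPM). The bounds for Agt and Akr1cl thus rest on 2 libraries. These were near-identical (root mean square log2 difference 0.115) and are not shown to be separate animals. In all, 1470 genes were called, 951 higher and 519 lower, of 5526 with an unadjusted p under 0.05. The count was 12 with near-identical libraries joined, 238 without knock-in library 2 and 3676 in a fit of only these groups, and 8 of the 10 refits without 1 library moved it by over 1.5 times.

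**Figure D4:**
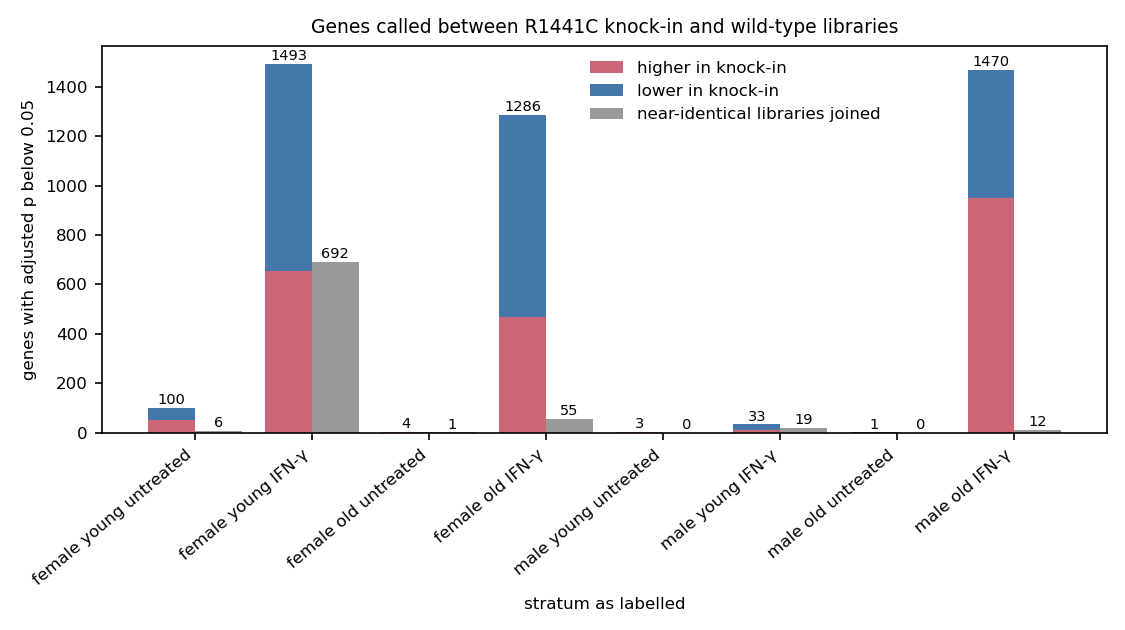
Number of genes called between knock-in and wild-type libraries in each stratum as labelled, higher and lower in knock-in, beside the number after near-identical libraries of a group were joined. The largest counts, 1493, 1286 and 1470, become 692, 55 and 12, where the groups of the first had no libraries to join.

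Irak4 was the only gene called in the same direction in at least 6 of the 8 strata. It was lower in knock-in in each, by log2 changes from -0.34 ± 0.08 (untreated males labelled young, adjusted p = 0.105) to -0.66 ± 0.06, with means of 34.6 to 46.9 CPM in knock-in and 50.7 to 62.0 CPM in wild-type, and it was called in 7. The libraries of the genotypes did not overlap in any stratum, for which chance gives 10% with 3 libraries against 3. Irak4 lies on the same chromosome as Lrrk2, within 5 Mb. Of the 253 tested genes within 10 Mb of Lrrk2, the share called did not differ from that of other genes in any stratum (Fisher's exact test, adjusted p from 0.0914 to 0.80). Within 5 Mb (61 tested genes) it was higher in each of the 8 strata (Fisher's exact test, adjusted p from 2.84e-04 to 0.011), as in males labelled old and IFN-γ, where 14 of 61 genes (22.9%) were called against 6.59% of other genes, and within 20 Mb it differed in 0 of 8. In untreated females labelled old and in untreated males of both labelled ages, only 1 of the 61 genes was called. Those 61 genes include Irak4, which was the 1 called in both untreated strata labelled old. With Irak4 left out, a choice made after the data were seen, the share within 5 Mb was higher in 5 of 8 strata (Fisher's exact test, adjusted p from 0.001 to 0.0474 in these). Among these, untreated males labelled young rested on 1 of 60 genes, against 2 of 22086 others. Across strata, 3794 genes were called in at least 1 stratum, 496 in the same direction in at least 2 and 13 in at least 3, among them Pdk4, a kinase that inhibits pyruvate dehydrogenase, with 4 (chosen after its values were seen). Fold changes of all genes correlated across genes at r = 0.561 between males labelled young and old with IFN-γ, at 0.499 between the corresponding females, and at -0.298 between young females without and with the IFN-γ label. Genes are not independent of each other. These strata share no libraries, but with 18 pairs past r 0.4 over V segments between labelled ages they are not shown to hold separate animals. Of the lists that address the study's question, 40 phagocytic receptors and opsonins and 24 genes of LRRK2 and its Rab partners passed the list test in 0 of the 8 strata by camera, with adjusted p from 0.109 to 0.987 and from 0.104 to 0.932.

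**Figure D5:**
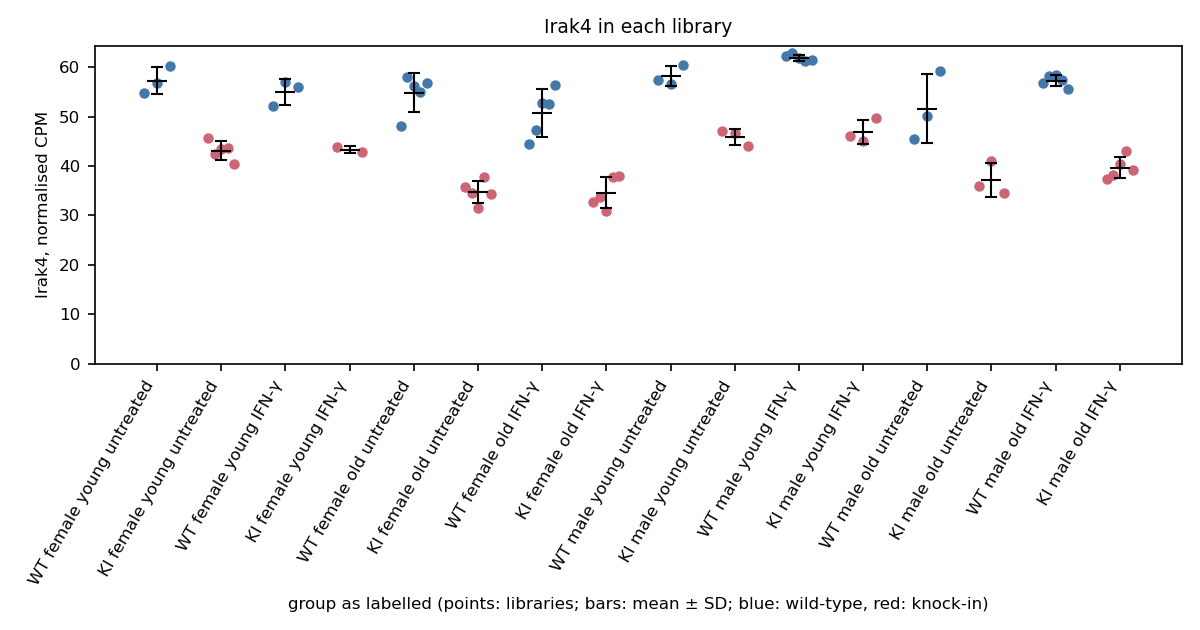
Irak4 in CPM by labelled group, with points for libraries (blue wild-type, red knock-in) and bars for mean ± SD. Means are 34.6 to 46.9 CPM in knock-in and 50.7 to 62.0 CPM in wild-type groups.

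Interactions tested whether the genotype effect differed between labels. For treatment in females labelled young, genes of the IFN-γ response and antigen presentation had a lower change with the IFN-γ label in knock-in than in wild-type. Of 37 IFN-γ response genes 29 were lower and 1 higher (30 and 1 adjusted over the list alone; median -2.45; adjusted p = 0.06 with an estimated correlation), with Ifi47 at -3.02, and of 14 MHC class II genes 9 were lower (9 adjusted over the list alone), with Cd74 at -2.65 ± 0.41 (adjusted p = 2.62e-05). The MHC class II call held with an estimated correlation (adjusted p = 0.0457). Wild-type IFN-γ library 1, with 8.13 over that list (6.87 and 7.52 in the others of its group), was also high in B cell and monocyte markers, as given above. The activity-dependent transcription factor Npas4 (2.90), Adam33 (2.64) and the nuclear RNA Neat1 (2.63) had the largest positive values and Serpinb2 (-5.79), the growth factor binder Igfbp3 (-5.62) and Ptgs2os2 (-5.48), which is antisense to Ptgs2, the largest negative ones. This interaction called 2527 genes, 1341 higher and 1186 lower, with 1122 and 1590 by RLE scaling and 990 and 1842 by DESeq2, and 771 in all without knock-in IFN-γ library 1.

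For treatment in females labelled old, oxidative phosphorylation genes were higher in 61 of 75 (73 adjusted over the list alone; adjusted p = 0.736 with an estimated correlation), with Cox8a at 0.57 ± 0.12 and Ndufs8 at 0.65 ± 0.14, and B cell markers were lower in 7 of 22 (14 adjusted over the list alone; adjusted p = 0.736 with an estimated correlation), with Cd79a at -2.50 ± 0.76. Ribosomal protein genes moved likewise, with 19 of 75 higher (56 adjusted over the list alone; adjusted p = 0.736 with an estimated correlation). Knock-in untreated libraries 1, 2 and 3 were low in both lists, at a mean log2 CPM of 5.88, 5.97 and 6.12 over oxidative phosphorylation (6.35 and 6.29 in 4 and 5, 6.25 to 6.45 in wild-type) and 7.57, 7.72 and 7.87 over ribosomal proteins (8.23 and 8.06; 8.04 to 8.30). With the IFN-γ label, Cd79a was at 12.3 and 13 CPM in the doubted knock-in libraries 4 and 5, against 57.6 to 62.8 CPM in 1, 2 and 3. It was at 197 CPM in the doubted wild-type library 2, against 26.6 to 61.1 CPM in the others of that group. The receptor Gpr34 (1.63), the transcription factor Pou3f1 (1.5) and Mfge8 (1.37) were highest, and Serpinb2 (-4.37), the lipoxygenase Alox15 (-3.34) and Gpr174 (-3.33) lowest. It called 2392 genes, 1437 higher and 955 lower, against 979 and 1285 by RLE scaling and 1324 and 1725 by DESeq2. The count was 0 with near-identical libraries joined, 20 without the doubted libraries, 486 without knock-in untreated library 1 and 3912 without knock-in untreated library 4. In males, edgeR called 0 genes for the interaction with treatment at either labelled age, with 1016 (young) and 3689 (old) genes at an unadjusted p under 0.05 and 15 and 89 called by DESeq2. A fit of only the groups of the contrast gave 0 (young, 1309 at an unadjusted p under 0.05) and 844 (old).

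For age in females with the IFN-γ label, MHC class II genes had a higher change from labelled young to old in knock-in. Of 14 genes 8 were higher (9 adjusted over the list alone), with H2-DMb1 at 1.47 ± 0.24 (adjusted p = 6.26e-04) and Cd74 at 1.82 ± 0.38, and the list kept its call with an estimated correlation (adjusted p = 0.043). Wild-type young IFN-γ library 1, high in MHC class II (8.13), B cell (6.17) and monocyte (5.97) markers, is part of this contrast. Klrk1 (3.58), the Toll-like receptor Tlr12 (3.47) and Sectm1a (3.29) were highest, and the serotonin receptor Htr2a (-2.28), Lrrc9 (-1.70) and Ldhd (-1.54) lowest. Among untreated females, 6 of 14 MHC class II genes were lower (8 adjusted over the list alone; adjusted p = 0.389 with an estimated correlation), with Cd74 at -1.21 ± 0.32. There, Neat1 (2.08), Catsperg1 (1.73) and Ing4 (1.70) were highest and Ptgs2os2 (-2.70), Rmi2 (-1.81) and Ifi47 (-1.57) lowest. The interaction with age called 229 genes in IFN-γ females (193 higher, 36 lower) and 454 in untreated females (375 and 79). The counts were 1 without knock-in young IFN-γ library 1 and 703 without wild-type old IFN-γ library 2 for the former, and 0 without knock-in old untreated library 2 and 2059 without knock-in old untreated library 4 for the latter, which also was 0 with near-identical libraries joined. In males, edgeR called 0 genes untreated and 0 with IFN-γ, with 2090 and 946 at an unadjusted p under 0.05 and 3 and 1 called by DESeq2.

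Between sexes, the genotype effect differed for 56 genes among libraries labelled young and IFN-γ, 19 with a higher and 37 with a lower value in females. The chemokine Cxcl3 (-5.71), Shisa8 (-5.30) and the neutrophil protease Prtn3 (-3.17) were lowest, and the taste transducin Gnat3 (2.75), Adam33 (2.11) and the GABA receptor subunit Gabbr2 (2.06) highest. Of 14 MHC class II genes 2 were lower, H2-DMb1 (-1.11) and Cd74 (-1.71; 9 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation). DESeq2 gave 44 higher and 307 lower, and the count was 4 without wild-type female 1 and 202 without wild-type female 5. With near-identical libraries joined 1 gene was called. Among libraries labelled old and IFN-γ, 12 genes were called, 2 higher, namely Atp9a (2.41) and Vill (0.88), and 10 lower, among which only the granzyme Gzmk (-2.96) was of a kind named here. That count was 3 without wild-type male 4 and 24 without wild-type female 1. Without the IFN-γ label, edgeR called 0 genes at either labelled age, with 2115 (young) and 2018 (old) at an unadjusted p under 0.05 and 1 and 13 called by DESeq2.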

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

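The tests of V segments, of RNA carried over, of overlapping libraries and of joined libraries, and the count of splits for young untreated females, were chosen only after the result was seen. The window of 5 Mb around Lrrk2 was fixed beforehand beside that of 10 Mb, and was taken for the test of flanking sequence after calls near Lrrk2 had been seen. Libraries far from the others of their labelled group were sought in 96 combinations of a measure (total counts or a gene) and a group of 5 libraries. Smaller groups were not searched. Of these, 8 stood apart, where chance gives about 1 in 20, or 4.8, for genes chosen beforehand. Slpi, Trpm5 and Ptgds were named for their changes in these data, so that number does not apply to them.

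Among wild-type males labelled young and IFN-γ, library 1 held 662 CPM of Gbp2, against 235 to 287 CPM in the others. In untreated wild-type females labelled old, library 1 stood apart in 3 genes, with 4070 CPM of Cxcl9 (others 1090 to 1550), 907 CPM of Nos2 (121 to 147) and 6.47 CPM of Cd79a (1.42 to 2.03). Library 2 of the wild-type females labelled old and IFN-γ held 197 CPM of Cd79a (26.6 to 61.1) and 2200 CPM of Slpi (111 to 150). Knock-in library 3 of the same label had 6.36 CPM of Trpm5 (0.0329 to 1.7), and knock-in male 2 labelled old and IFN-γ had 0.0106 CPM of Ptgds where the others had 0. That last value is near the limit of counting.

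The genotype effect differed between labels, by a test of the interaction itself, for 2527 genes with treatment in females labelled young, 2392 with treatment in females labelled old, 454 with age in untreated females, 229 with age in IFN-γ females, and 56 and 12 with sex among IFN-γ libraries labelled young and old. Each of these counts moved by over 1.5 times when 1 library was left out. They fell to 771 without knock-in young IFN-γ female 1, to 486 without knock-in old untreated female 1, to 0 without knock-in old untreated female 2, to 1 without knock-in young IFN-γ female 1, to 4 without wild-type young IFN-γ female 1 and to 3 without wild-type old IFN-γ male 4, in that order. Other libraries that did so are counted in the next part.

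Genes that respond to IFN-γ followed the age label in each of 63 libraries for Gbp2. Age as labelled on different animals is argued against by the V segments, since the highest r between libraries labelled with different ages was 0.94 where pairs that differed in genotype or sex reached 0.38. RNA carried over from libraries labelled old into those labelled young is argued against as well. The median of observed over required Gbp2 in the library labelled young was 0.0688 over 18 pairs (highest 0.234). Carry-over the other way was not tested, since it need not raise Gbp2 there, and it could pair V segments with age as labelled. A candidate explanation is that the age and treatment labels were exchanged, so that libraries labelled old and young would be treated and untreated cells of the same animals, for which 18 pairs passed r 0.4. It stays a hypothesis, since 0 of 58 pairs labelled untreated passed, which goes against it for those libraries. V-segment counts were few there, but a pair within an untreated group passed (r 0.451 at 1371 and 1445 counts), as did simulated pairs at like counts. Few counts alone may thus not account for the 0, and an effect of age beside the exchange is untested.

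Of the genes called at over 2-fold between the genotypes in groups labelled IFN-γ, the libraries of both genotypes overlapped in 70.9% in females labelled old and in 51% in males labelled old, so that a minority of libraries may carry these calls, while 13.1% in females labelled young decided neither way. Joining near-identical libraries left 55 and 12 calls in old females and old males, fewer than any of 20 random joinings of as many libraries (lowest 120 and 13). Random joinings average unlike libraries and can narrow the spread by themselves, and each also joined near-identical pairs (2 to 10). The comparison thus cannot decide whether near-identical libraries counted as separate replicates add to these calls. In young females the joined count, 692, says nothing on this, since their groups had no libraries to join and the count moved only through other groups of the fit. The lowest joining of old males differed by 1 gene from the value, and fewer libraries by themselves lowered the counts, to random medians of 177 and 89. An effect of the R1441C change, which the design names, stays open beside these.

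Irak4 was lower in every knock-in group. Flanking sequence of the donor strain around the knock-in may account for it: of the other genes within 5 Mb of Lrrk2, 3 of 60 (5.00%) had the same sign in all 8 strata against 188 of 22085 (0.851%), an odds ratio of 6.13 (Fisher's exact p = 0.0151), but the ratio was 1.39 within 10 Mb (exact p = 0.482) and 1.33 within 20 Mb (exact p = 0.469). Those 3 genes were Slc38a1 (-0.61 to -0.12) and 2 antisense genes, A130051J06Rik (-1.63 to -0.74) and Gm49173 (-5.05 to -0.83), so the test rests on few genes. A strain difference spread over the genome was not decided, with 0.862% of genes of the same sign against 0.781% for random signs. An effect of the R1441C change on Irak4 stays open and was not tested.

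Other splits of the same libraries were counted for each contrast with 3 or more libraries per group, with the real split included and each library treated as exchangeable. Near-identical libraries breach that premise (48 units among 63 libraries) and the contrasts were not adjusted for each other, so the shares below do not exclude chance. Under 0.05 of the splits called as many genes for the genotype effect in untreated females labelled young (100 genes, highest other split 331, 2 of 56 splits as large). The same held in females labelled old and IFN-γ (1286, highest other 2891, 2 of 100) and in males labelled old and IFN-γ (1470, highest other 62, 1 of 100). The share was 0.05 or more in untreated females labelled old (4, highest other 3380, 14 of 100) and in males labelled young and IFN-γ (33, highest other 213, 8 of 56). For untreated males the 10 splits are too few for a share under 0.05, with 3 genes labelled young (highest other 70, 2 splits as large) and 1 labelled old (highest other 0, 1 split as large). With near-identical libraries joined, the 3 counts with a share under 0.05 were 6, 55 and 12, so those shares do not carry over to animals. Splits that called several times the real number, as in untreated females labelled young and old and males labelled young, point to a structure of the samples other than genotype, and 1 other split in females labelled old and IFN-γ called over 2 times as many.

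For the IFN-γ label in wild-type, under 0.05 of the splits called as many genes (6939, highest other split 861, 1 of 100), on the same breached premise. Between the age labels the share was also under 0.05 in wild-type females (9861, highest other 5509, 1 of 56) and knock-in females (9917, highest other 6280, 1 of 100). The 10 splits are too few in wild-type males (8163, highest other 0, 1 split as large) and knock-in males (7110, highest other 1958, 1 split as large). For interactions, the share was under 0.05 for treatment in females labelled old (2392, highest other 3793, 3 of 100), though the highest other split called more genes than the real one. There edgeR called 0 genes with near-identical libraries joined (4117 at an unadjusted p under 0.05), 0 in a fit of only these groups (4671) and 20 without the doubted libraries, and DESeq2 with all libraries called 3049. The share was 0.05 or more for age in untreated females (454, highest other 3328, 9 of 100) and for sex among libraries labelled old and IFN-γ (12, highest other 728, 8 of 100), where splits calling several times the real number again point to a structure of the samples. The 6 interactions in which edgeR called 0 genes had 100 of 100 splits as large. Their highest other splits were 83 and 4 (treatment, males labelled young and old), 214 and 188 (age, males untreated and with IFN-γ), and 681 and 791 (sex, untreated, labelled young and old), at 1016, 3689, 2090, 946, 2115 and 2018 genes with an unadjusted p under 0.05 and 15, 89, 3, 1, 1 and 13 by DESeq2. Contrasts that include the 2 knock-in young IFN-γ females had no count of splits.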

How the results depend on the processing

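The settings with near-identical libraries joined, without 4 doubted libraries and that near Lrrk2 with Irak4 not counted were chosen only after the data were seen. The counts between age labels stayed within 1.5 times in every setting run, as did that of the IFN-γ label in wild-type except when near-identical libraries were joined. Calls of named genes were counted once for each gene and contrast, so a gene may count several times. Of these, 156 of 156 were kept in every setting for the age label, 73 of 80 for the IFN-γ label and 11 of 28 for genotype by treatment. For genotype 8 of 111 were kept (46 of 111 when libraries were joined), for genotype by age 0 of 12 and for genotype by sex 0 of 9. Unless the setting itself shows it, the cause was not tested. Counts in the order young untreated, young IFN-γ, old untreated, old IFN-γ were 100, 1493, 4 and 1286 for genotype in females and 3, 33, 1 and 1470 in males.

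Without a filter, which tests more genes, the genotype counts were 49 (young untreated females), 753 (old IFN-γ females), 0 (young untreated males) and 583 (old IFN-γ males), and the interactions 1344 (treatment, old females), 155 and 136 (age, untreated and IFN-γ females) and 30 (sex, young IFN-γ). RLE factors moved old untreated females to 41. DESeq2 gave 352, 396, 13 and 3 for genotype in young and old untreated females and males, 15 and 89 for treatment in young and old males, 821 and 805 for age in untreated and IFN-γ females, 3 and 1 in the corresponding males, and 1, 351, 13 and 32 for sex (young untreated, young IFN-γ, old untreated, old IFN-γ).

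A fit of only the groups of each contrast, which leaves fewer libraries to estimate the spread, gave 419, 0, 2 and 3 for genotype in females and 0, 288, 0 and 3676 in males, in the order above. It gave 1336 and 0 for treatment in young and old females, 844 in old males, 0 and 55 for age in untreated and IFN-γ females and 0 for sex (old IFN-γ).

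With near-identical libraries joined, which leaves 48 libraries (2 to 5 per group), the genotype counts were 6, 692 (no library of these 2 groups joined), 1 and 55 in females and 0, 19, 0 and 12 in males. Counts for the IFN-γ label were 3421 (wild-type) and 1108 (knock-in), and the interactions 1333 and 0 (treatment, young and old females), 0 and 50 (age, untreated and IFN-γ females) and 1 and 0 (sex, young and old IFN-γ). Without the doubted libraries, counts were 916 and 380 (genotype, young and old IFN-γ females), 3008 (IFN-γ label, knock-in), 20 (treatment, old females) and 192 (sex, young IFN-γ).

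The replicate number as a block gave genotype counts of 15, 984, 2 and 660 in females and 12 and 591 in young untreated and old IFN-γ males, 1370 and 5 for treatment in young females and males, 997 for age in untreated females and 88 for sex (young IFN-γ). With the block, Lrrk2 in old untreated males reversed from -0.11 to 0.0471 (not called). Libraries with the same replicate number were more alike than others across labelled treatment (mean r 0.18 against -0.044, permutation p = 0.0017) and labelled age (0.228 against -0.0518, permutation p = 0.0051) but not shown to be across genotype (0.0184 against -0.0122, permutation p = 0.391). Of 26 pairs each, 16, 19 and 12 had an r above 0.1, and the best match was the own number for 26, 24 and 11 of 52 libraries. Since not every pair passed 0.1, the numbers were not taken as pairing over the design, but in part of it they may. Across labelled age all pairs passed in untreated wild-type females (r of 0.38 to 0.623, 9982 genes with the block), in IFN-γ males of both genotypes and in untreated knock-in males (0.362 and 0.45). Across labelled treatment they passed in old wild-type males and in young knock-in females (0.176 and 0.317). Across genotype the only pair of young untreated males passed (0.395). Gene lists were not tested with the block.

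Leaving out 1 library gave genotype counts of 3 (without wild-type 1) to 411 (without wild-type 5) in young untreated females, 105 (knock-in 1) to 2220 (wild-type 2) in young IFN-γ females, 1 (knock-in 1) to 2788 (knock-in 4) in old untreated females and 140 (wild-type 2) to 2587 (wild-type 4) in old IFN-γ females. In males they were 0 (knock-in 2) to 31 (knock-in 3), 11 (knock-in 3) to 58 (wild-type 1), 0 (knock-in 2) to 1 and 238 (knock-in 2) to 1419 (wild-type 2). The IFN-γ label in knock-in ran from 1052 (young IFN-γ female 1) to 2104. Treatment interactions ran from 771 (knock-in IFN-γ 1) to 3119 in young females, 486 (knock-in untreated 1) to 3912 (knock-in untreated 4) in old females, 0 to 10 (knock-in untreated 3) in young males and 0 to 1 (knock-in untreated 5) in old males. Age interactions ran from 0 (knock-in old 2) to 2059 (knock-in old 4) in untreated females, 1 (knock-in young 1) to 703 (wild-type old 2) in IFN-γ females and 0 to 1 (knock-in old 1) in IFN-γ males, and those with sex from 4 (wild-type female 1) to 202 (wild-type female 5) in young and 3 (wild-type male 4) to 24 (wild-type female 1) in old IFN-γ libraries. These name the extremes, and 6 of 8, 3 of 5, 10 of 10 and 7 of 10 refits moved the genotype count by over 1.5 times in females and 6 of 6, 7 of 8, 3 of 6 and 8 of 10 in males. For the interactions 3 of 13 (treatment, young females), 10 of 20 (old females), 16 of 18 (age, untreated females), 7 of 15 (IFN-γ females), 9 of 13 (sex, young IFN-γ) and 11 of 20 (old IFN-γ) did so. Log2 values that were not called and reversed without 1 library were Lrrk2 in old untreated males (-0.2896 without wild-type 5 to 0.0584 without wild-type 1), and in the IFN-γ effect in knock-in Htr2b (-0.1938 without young IFN-γ female 1 to 0.0995 without old untreated male 4, above 0 in 4 refits) and Ctsk (-0.0984 without young IFN-γ female 1 to 0.0287 without young IFN-γ male 2, above 0 in 3).

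The preset correlation called 325 tests of gene lists, the fry test 171 and an estimated correlation 23. The share of genes called near Lrrk2 differed in 0 strata within 10 Mb in 8 within 5 Mb and in 5 within 5 Mb with Irak4 not counted. Depth was 73.6 M counts or more, and limits transcripts such as Ptgds in knock-in males, where 0.0106 CPM rests on about 1 count. In simulated counts at these depths 62% of genes changed 1.5-fold were recovered for genotype in young untreated females.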

Other observations

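The tests in this part were all chosen only after the result was seen, and the values below are given as found. Transcripts at 1 CPM or more in at most 8 libraries (194 transcripts) came in sets. In 4 libraries of wild-type males labelled IFN-γ, old 4 and 5 and young 4 and 5, Ptgds was at 12.1, 11, 10.7 and 10.7 CPM (next library 0.0674), Agt at 10.2, 9.61, 9.86 and 10.6 CPM (next 0.0303), Hsd3b6, a steroid dehydrogenase, at 1.81, 1.26, 2.02 and 1.8 CPM (next 0.03) and the sperm protamine Prm2 at 1.75, 2.37, 4.52 and 3.99 CPM (next 0.176). In wild-type males these libraries held the high values of Ptgds, Agt and Prm2, which were called lower in knock-in males.

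In females, Trpm5 was highest in knock-in IFN-γ libraries young 2 (11.5 CPM), old 3 (6.36), young 1 (2.82), old 1 (1.7) and old 2 (1.68), followed by wild-type young 2 (1.01). Knock-in IFN-γ libraries old 4 and 5 were at 0.0329 and 0.0621 CPM. Over V segments, knock-in young 1 had an r of 0.881 and 0.857 with old 1 and 2, and young 2 of 0.663 with old 3. The Trpm5 calls in females labelled young and old are thus not shown to come from separate animals. Slpi was at 2200 CPM in wild-type IFN-γ library old 2 and at 1430 CPM in young 1 (next 249), Serpinb2 at 83.1 and 344 CPM (next 18.1) and Lepr at 2.34 and 31.1 CPM (next 0.804). The same pair of libraries shared 33 of the 194 transcripts and had the highest r over V segments, 0.944. Sharing of 5 or more was seen in 8 of 123 pairs that differed in labelled age only, 3 of 102 pairs of the same group, 0 of 123 that differed in labelled treatment only, 0 of 119 that differed in both and 8 of 1486 that differed in genotype or sex.

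Of 102 pairs of libraries within groups, 16 lay under a root mean square log2 difference of 0.17, where the median was 0.284. The first principal component held 64.49% of the variance and the second 12.32%. The 3 knock-in males labelled old and untreated for which another field names IFN-γ (2, 4 and 5) had 6173, 5499 and 6808 CPM of Gbp2 before TMM scaling. The other libraries labelled old and untreated were at 5463 to 6874 CPM, so these levels cannot tell which field is right. Knock-in females 4 and 5 labelled old and IFN-γ, which had little Xist and little Ddx3y, matched neither sex by these genes.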
